A study of Mus musculus with 7 samples.

How the data were processed

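Chromatin accessibility was measured by Omni-ATAC-seq, in which a transposase cuts and tags open DNA, on haematopoietic stem cells of mice. Per the labels, bone marrow enriched for cKit-positive cells was taken from C57BL/6 donors aged 24 months. It was infected with a control lentivirus or one expressing Runx3, a transcription factor of the RUNX family, and transplanted into lethally irradiated recipients. Transduced donor-derived stem cells (LSK, negative for Flt3 and CD48, positive for CD150, CD45.2 and hCD2) were sorted 16 weeks later. The 7 libraries fall into 4 control libraries, numbered 1, 2, 3 and 4, and 3 Runx3 libraries, numbered 1, 3 and 4. The labels do not say whether libraries came from separate recipients or donors, so p-values measure the spread between these samples, which may be partly technical.

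The deposited table holds raw read counts per peak, whole numbers without normalization, for 98723 peaks that do not overlap. Per the submitters' processing notes, Trim Galore, FastQC, Bowtie2, SAMtools, Picard and MACS2 were used with the mm9 build. Their versions, roles and order, the way the shared peak set was made, and any shift of reads for the transposase are not given in the sources used here. Coordinates are those of the table, in mm9. The table does not say whether starts are counted from 0 or 1, so a start may be off by 1 base. A gene table of another build, GRCm38.p6, was at hand, and on 9 of 21 chromosomes peaks ended beyond its last gene. Its coordinates were not used. Gene names, promoter distances, motifs, GC content, the Runx3 locus and gene lists were therefore not analysed here.

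Counts were tested with edgeR 4.0.16 in R 4.3.3. Peaks were kept by filterByExpr (minimum count 10, minimum total 15), which left 57504 peaks holding 91.6% of counts. Libraries were scaled by TMM. The quasi-likelihood test with robust estimation compared all 7 libraries by vector, without a block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic, which is approximate. CPM, the counts scaled to a common library size, are TMM-normalised, and values are means ± SD over libraries. On simulated counts for the same 57504 peaks, 50 peaks with a mean count of at least 10 were changed at each size. The test recovered 11 at 1.5-fold, 29 at 2-fold, 44 at 3-fold and 45 at 4-fold. It made 3 false calls among 132. The simulated peaks varied independently, without differences between libraries shared by many peaks, and peaks of like depth were given the same variability. Weaker peaks were not among the changed ones. These rates may therefore be too favourable for the real libraries.

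Total counts per library ran from 1738164 to 3758422, and the Runx3 libraries were on average shallower (mean 2238860) than the control libraries (mean 3113950). A count of 3 corresponds to between 0.798 and 1.73 CPM, depending on the library. Intervals cover counting or model error only, since the counts carry no molecular identifiers. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 1.18 to 2.25), so none was treated as a second copy of another. This does not show that they come from separate animals.

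The labels give no batch. Every division of the libraries into 2 parts was scanned for peaks at least 8-fold apart with a pseudocount of 0.5 CPM, and control 1, control 2 and Runx3 1 shared 54 peaks that were nearly absent from the rest, while no other division gave more than 1. These libraries are called set 1 and the other 4 set 2. The sets were found from the data, cut across the vector groups, and were used for values within each set and as a term in an added fit.

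The peaks named in the text were chosen by a rule fixed before the data were examined: per direction, the 12 called peaks with the smallest p whose groups did not overlap, at most 1 per 100 kb. Any other peak or region singled out was chosen after its values were seen. Chromosome shares of counts were compared by a two-sided exact permutation test over the 35 ways of choosing 3 of 7 libraries. Windows of 1 Mb with at least 5 tested peaks were tested for called peaks against a binomial expectation. Alternatives covered normalization, filters, DESeq2 1.42.0, limma-voom (limma 3.58.1), thresholds, a replicate block and leaving out each library. Those added after seeing the data were the library sets, the removal of the 54 peaks, DESeq2 on the peaks edgeR tested, and depth thinning or a depth covariate.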

Results

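The comparison asked which stretches of open chromatin differ in stem cells of aged donors that carried the Runx3 vector through transplantation. Total counts in peaks were 2188113, 2799286, 3709974 and 3758422 in control libraries 1 to 4, and 1738164, 2576715 and 2401700 in Runx3 libraries 1, 3 and 4.

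Few peaks passed the test. With Runx3, 19 peaks were more accessible and 23 less accessible among 57504 tested, which is 0.0730% of them (edgeR quasi-likelihood test, adjusted p under 0.05). The changes at these sites were between 1.72-fold and 7.0-fold, with a median absolute log2 fold change of 1.42. The median log2 fold change of all tested peaks was -0.01. The scaling of libraries largely fixes this value, so it does not show whether accessibility shifted as a whole. At an unadjusted p under 0.05 there were 4777 peaks. The 34 other ways of choosing 3 of the 7 libraries gave between 1393 and 5500 such peaks, and 1 of them gave more than the real grouping. At the adjusted threshold, other groupings called up to 88 peaks against 42 for the real one, so chance is not excluded for this number. The grouping with 88 separates set 1 from set 2, and 43 of its peaks are among those that define the sets. The next, with 84, also gave the 5500. It differs from the real grouping only by placing control 1 with the Runx3 libraries, so it keeps much of the vector contrast. These groupings are therefore not arbitrary ones. In all 42 called peaks the 3 Runx3 libraries lay entirely above or below the 4 control libraries. That held for 8.94% of tested peaks. The average over all 35 ways of choosing 3 libraries is 5.71% for peaks without tied values. How far single ways spread around it was not computed, so an excess over chance is not shown.

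The peak with the smallest p was less accessible with Runx3. It lies on chromosome 5 at 140252899 to 140253508 and fell from 15.9 ± 3.75 CPM in controls (SD, n = 4) to 4.23 ± 1.19 CPM (SD, n = 3), a log2 fold change of -1.86 ± 0.29 (SE, edgeR adjusted p = 0.0057). The largest drop was on chromosome 12 at 116446187 to 116446481, from 6.87 ± 2.76 to 0.954 ± 0.753 CPM, or 7.0-fold (edgeR adjusted p = 0.020). That Runx3 mean lies below the level of 3 counts in any Runx3 library, so the size of this drop is poorly fixed, and its log2 fold change went from -2.81 to -3.69 without Runx3 4. A second peak of chromosome 12, at 116699016 to 116699724, fell from 14.6 ± 3.24 to 5.50 ± 0.465 CPM. On chromosome 17, 3 named peaks were lower. The peak at 34347421 to 34348109 had 24.3 ± 3.18 CPM in controls and 10.9 ± 2.89 with Runx3. The peak at 7279740 to 7280295 was 2.66-fold lower and the peak at 8243046 to 8243494 was 2.44-fold lower.

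Chromosome 9 also held 3 of the named lower peaks. At 61169729 to 61170590 accessibility fell from 22.3 ± 8.50 to 8.12 ± 1.14 CPM, and at 121586111 to 121586619 from 16.3 ± 1.86 to 6.64 ± 1.59 CPM. The named peak with the highest mean in controls, at 115617331 to 115618319, fell from 31.6 ± 6.12 to 16.9 ± 1.56 CPM, or 1.89-fold. The other named lower peaks were on chromosome 1 at 92976801 to 92977307 (3.13-fold lower), on chromosome 10 at 74599911 to 74600405 (2.37-fold lower) and on chromosome 13 at 98894184 to 98895183 (2.23-fold lower).

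Among the peaks that gained accessibility, the smallest p was on chromosome 7 at 105713162 to 105713755. It rose from 6.87 ± 0.870 CPM (SD, n = 4) to 18.4 ± 4.19 CPM (SD, n = 3), a log2 fold change of 1.41 ± 0.23 (SE, edgeR adjusted p = 0.0085). On the same chromosome the peak at 27564858 to 27565132 rose 4.28-fold, from 4.47 ± 2.04 to 18.6 ± 8.39 CPM. With the total count as a covariate, its log2 fold change went from 2.10 to 1.31 and no longer passed. The peak on chromosome 14 at 121501761 to 121502272 rose from 8.69 ± 1.58 to 21.3 ± 2.87 CPM. On chromosome 8, the peak at 81266316 to 81266910 rose from 7.21 ± 0.461 to 17.2 ± 2.04 CPM, and the peak at 124094074 to 124094716 from 11.6 ± 3.12 to 33.5 ± 14.1 CPM.

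On chromosome 10, named peaks at 21977736 to 21978602 and at 22167976 to 22168808 rose 2.24-fold and 2.69-fold, and a called peak that the rule did not name, at 118390953 to 118391420, rose 2.83-fold. On chromosome 5, peaks at 15061908 to 15062552 and at 16974466 to 16975289 rose 4.86-fold and 3.12-fold, both from low control levels of 1.55 ± 0.687 and 3.33 ± 0.649 CPM. The remaining named higher peaks were on chromosome 13 at 12198172 to 12199401 (2.22-fold), on chromosome 17 at 19795448 to 19795754 (4.21-fold) and on chromosome 18 at 65116860 to 65117621 (2.97-fold). The log2 fold change of the chromosome 17 peak went from 2.08 to 1.26 with the total count as a covariate and no longer passed. Under that covariate 14 of the 24 named peaks no longer passed. The 18 called peaks that the rule did not name were 7 higher and 11 lower. They include peaks of the same 1 Mb window of chromosome 15 that moved in opposite directions. The peak at 79524943 to 79525259 was 2.57-fold lower and that at 79597873 to 79598471 was 2.08-fold higher.

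**Figure D1:**
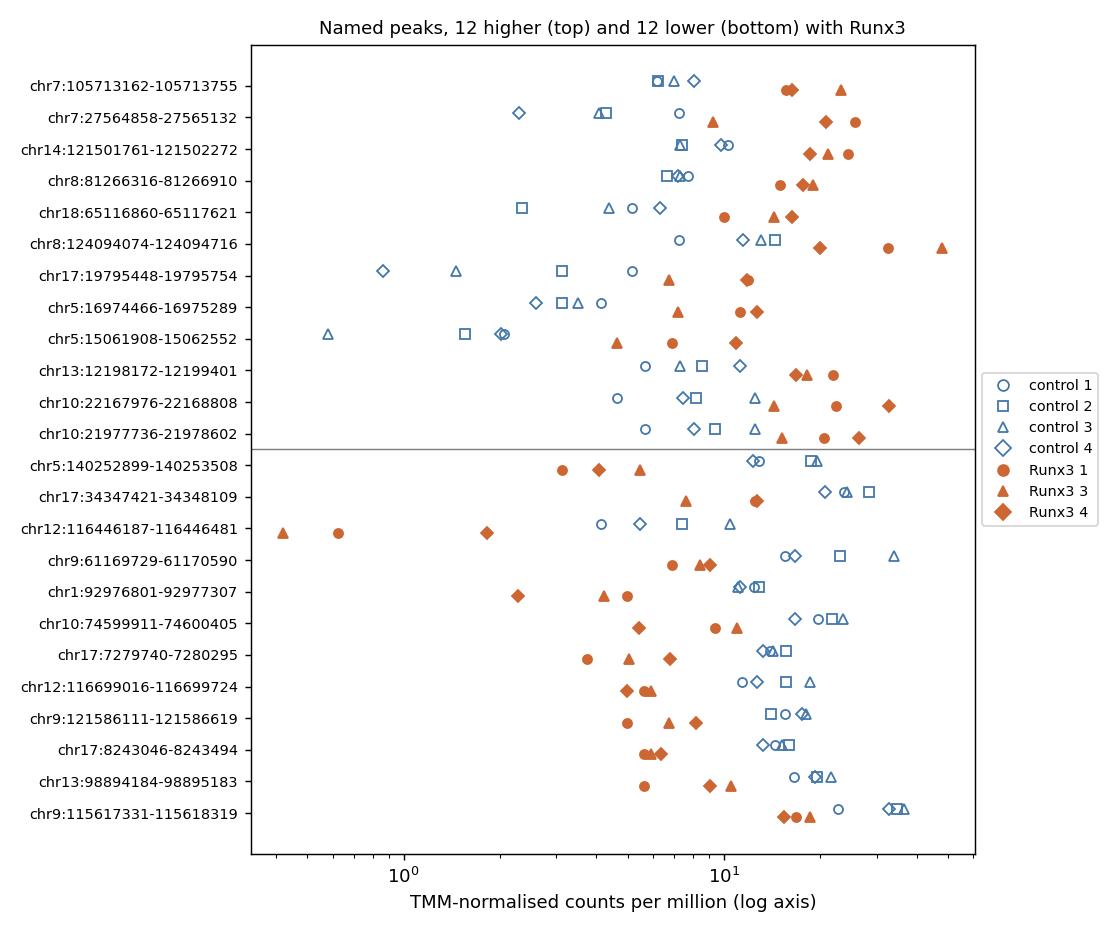
Accessibility of the 24 named peaks in each library, as TMM-normalised CPM on a log axis, with open symbols for the 4 control libraries and filled symbols for the 3 Runx3 libraries. In every peak the libraries of the groups do not overlap, and the widest gap is at chromosome 12, 116446187 to 116446481, where controls average 6.87 CPM and Runx3 libraries 0.954 CPM.

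The number of calls depended on single libraries and on the tool. Without control 2, or without Runx3 1, edgeR called 0 peaks (3739 and 4475 at an unadjusted p under 0.05), without control 1 it called 73 higher and 194 lower, and DESeq2 on all 7 libraries called 2 higher and 1 lower.

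The size of the changes was also estimated within set 1 (control 1 and 2 against Runx3 1) and within set 2 (control 3 and 4 against Runx3 3 and 4), which share no library. Since the groups of all 42 called peaks do not overlap, their sign in each set was fixed in advance and is no separate evidence. The peak at chromosome 5, 140252899 to 140253508, had a log2 fold change of -2.34 in set 1 and -1.72 in set 2, and the peak at chromosome 7, 105713162 to 105713755, had 1.32 and 1.40. Fitted with the set as a term, 22 peaks were higher and 29 lower, and 40 of the 42 were again called.

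Calls made in 1 set could be followed in the other. Set 2 alone called 29 higher and 72 lower peaks. Of the 29, 24 were also higher in set 1 (82.8%, exact 95% binomial interval 64.2 to 94.2), where 48.2% of all tested peaks were higher. Of the 72, 56 were lower in set 1 (77.8%, interval 66.4 to 86.7), where 51.8% of all tested peaks were. The intervals of this paragraph treat peaks as independent. Every direction in set 1 rests on the same libraries, with a single Runx3 library, so the intervals do not measure how well a vector effect repeats. Set 1 alone, with a single Runx3 library assumed to vary like the controls, called 5 higher and 18 lower. All 5 were higher in set 2 (exact 95% binomial interval 47.8 to 100) and 5 of the 18 were lower there (27.8%, interval 9.69 to 53.5). Of the 18, 17 had 5 reads or fewer in every library of set 2, so that their direction there is poorly read, and 10 belong to the 54 peaks that define the sets. No peak had a difference between the sets in its response to Runx3 at an adjusted p under 0.05 in edgeR (2708 at an unadjusted p under 0.05).

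**Figure D2:**
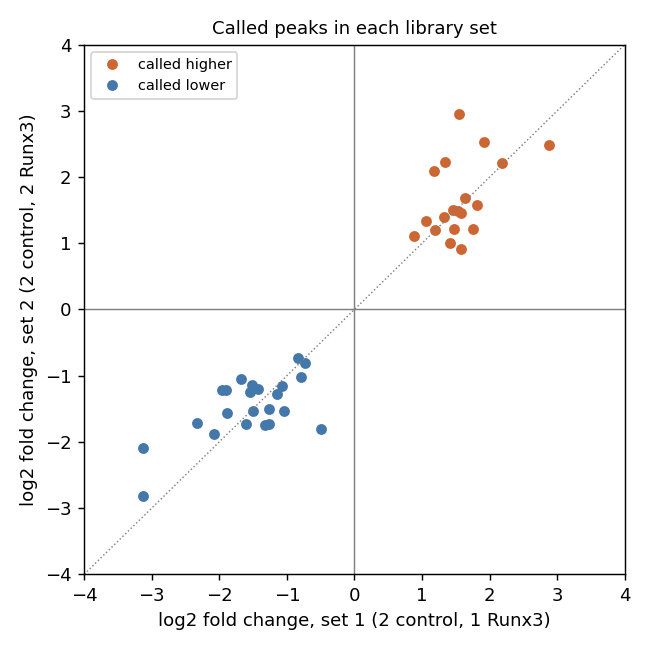
Log2 fold change of the 42 called peaks in set 1 (horizontal axis) and in set 2 (vertical axis), with a dotted line where both are equal. The signs match by construction, since the groups of these peaks do not overlap, so the plot shows sizes only, for example 1.32 and 1.40 at chromosome 7, 105713162 to 105713755.

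The most accessible sites held few of the calls. Ranked by accessibility into 5 classes of equal size, the most accessible class (median 41.8 CPM) held 0 higher and 2 lower called peaks, and 4.99% of its peaks had an unadjusted p under 0.05. The other classes had between 7.77% and 10.1%. The middle class, with a median of 9.48 CPM, held 5 higher and 10 lower calls.

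The share of counts per chromosome could not reach significance in this design, since 0.0571 is the smallest p that the exact test over 35 splits can give. The share of counts on the X chromosome was 1.71% ± 0.0328 (SD, n = 4) in controls and 1.75% ± 0.0393 (SD, n = 3) with Runx3 (two-sided exact permutation p = 0.34). Chromosome 6 came closest, with 5.07% ± 0.0464 of counts in controls (n = 4) and 5.12% ± 0.0313 with Runx3 (n = 3) over tested peaks (exact permutation p = 0.17). Over all peaks its share was 5.13% ± 0.0422 and 5.19% ± 0.0347, every Runx3 library lay above every control, and p was at the smallest value the exact test can give. The 3 peaks on the Y chromosome held between 3 and 18 counts per library.

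Called peaks did not pass the test for clustering, and 1 window of chromosome 12 held more than 1 called peak of the same direction. Between 116000001 and 117000000, 2 of 22 tested peaks were called lower where 0.0088 would be expected, with a binomial adjusted p of 0.14 over windows of 1 Mb. Another 11 of the 22 had a lower level at an unadjusted p under 0.05, for a total of 13, and none was higher at that level. The median log2 fold change of the 22 was -0.84, and it was -0.92 within set 1 and -0.74 within set 2. The window was singled out by calls from all libraries, so the values within each set are no separate evidence. The peak at 116383511 to 116384105 had a log2 fold change of -1.43 ± 0.31 (SE) and missed the threshold (edgeR adjusted p = 0.0504), and the peak at 116885756 to 116886711 had 0.22 ± 0.24. Summed counts of this window, or of any other, did not pass in edgeR (142 of 1949 windows at an unadjusted p under 0.05).

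**Figure D3:**
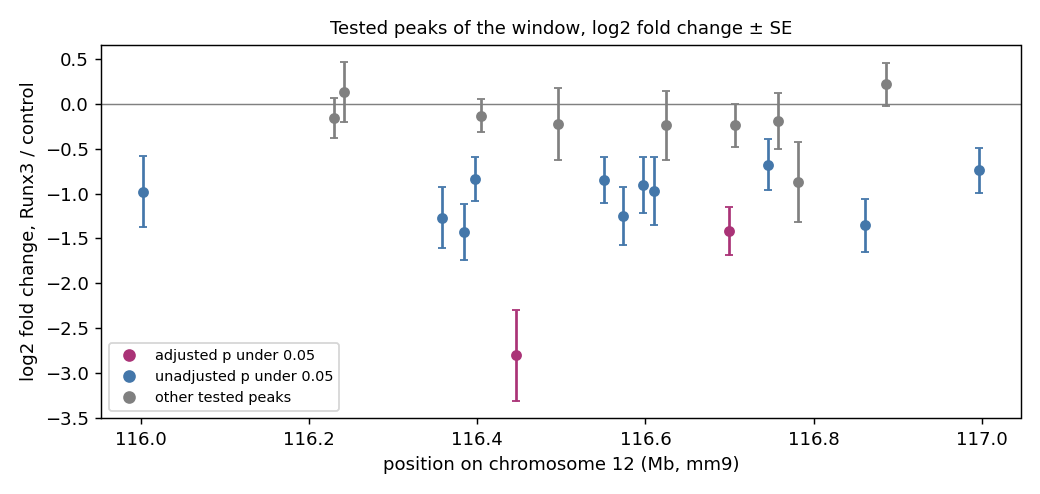
Log2 fold change (Runx3 over control) with its SE for the 22 tested peaks between 116000001 and 117000000 of chromosome 12, against position in Mb of mm9. The 2 called peaks have log2 fold changes of -2.81 and -1.42, 11 more are lower at an unadjusted p under 0.05, and the highest is 0.22.

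Control 1, control 2 and Runx3 1 shared 54 peaks that were nearly absent elsewhere. They took 0.423%, 0.233% and 0.137% of the counts in these 3 libraries, and at most 0.0034% in any library of set 2. The largest, on chromosome 17 at 4626089 to 4626667, had 1853, 1157 and 315 reads in the 3 libraries and at most 11 in each of the other 4. The 54 peaks lie on 19 chromosomes and are narrow, with a median width of 238 bases against 389 for all peaks. None of the 42 called peaks is among them, and leaving them out gave 23 higher and 28 lower calls.

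**Figure D4:**
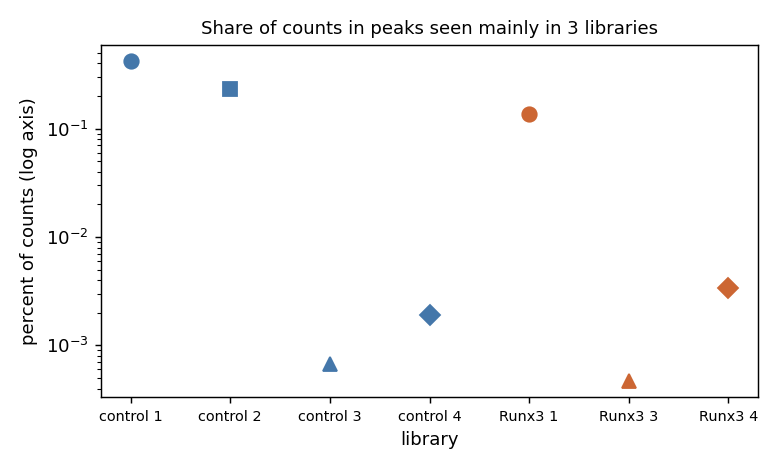
Percent of each library's counts in the 54 peaks shared by control 1, control 2 and Runx3 1, on a log axis. The 3 libraries lie at 0.137% or above and the other 4 at 0.0034% or below.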

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

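The tests of explanations in this part were all chosen after the results they bear on had been seen, and so was the window of chromosome 12.

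Control 1 stood apart from the other 3 controls. Its mean correlation with its own group was 0.893, where the nearest other control had 0.917. Its share of counts was the lowest of the controls on chromosome 13 (3.90%), 18 (2.84%), 3 (4.60%), 6 (5.0%) and X (1.67%), and the highest on chromosome 17 (5.48%). In each of these values its gap to the nearest control took most of the range of the 4. Of 48 values examined in this way 7 stood out, all in control 1, where chance gives about 2.4, and the values are not independent. No explanation was tested for this library.

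The low-count filter left out 41219 peaks. They were searched for a signal in a Runx3 library at least 8-fold above every control, with 0.5 CPM added to each level. A minimum number of reads in a Runx3 library was also required, so peaks with fewer reads were not listed. The search gave 2 peaks. The opposite pattern, a signal in a control above every Runx3 library, was not searched for. The peak on chromosome 1 at 12647575 to 12647814 had 26 reads in Runx3 4, 4 in Runx3 1, 2 in Runx3 3 and 0 in each control. The peak on chromosome 8 at 14306682 to 14307407 had 83 reads in Runx3 4, 32 in Runx3 1 and 9 in Runx3 3, with at most 7 in any control. Fitted without the low-count filter, neither passed (edgeR adjusted p = 0.31 and 0.50).

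The 54 peaks of set 1 do not follow the vector: control 1 held 0.423% of its counts in them, while Runx3 3 held 0.000466%. A genomic difference present at equal dose in the 3 libraries would share reads between them as ordinary peaks do, yet control 1 gave a median of 49.9% of the reads of these peaks and 31.9% of those of ordinary peaks. DNA of 1 source added to the 3 libraries in unequal amounts may account for both. It would also hold the ratio between the libraries constant, and the chi-square per degree of freedom of that ratio was 1.97, below the 4.57 of ordinary peaks of like depth but within their interval of 1.36 to 8.29, so this stays open. Without the 6 largest of the 54 it was 1.27, against 1.69 (1.18 to 2.15) for ordinary peaks matched to the other 48, which does not settle it.

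The library sets do not account for the lower peaks of chromosome 12 between 116000001 and 117000000. Their median log2 fold change was -0.84 with the set as a term. A uniform change in copy number of the window does not account for them by itself. The log2 fold changes differed by more than their errors (heterogeneity chi-square 86.5 on 21 degrees of freedom). These errors are approximate, and the window was chosen for its called peaks, which adds to the spread. A change in copy number of part of the window was not tested. With the total count as a covariate the median was -0.72. With libraries thinned to the smallest total, 16 of the peaks were tested, with a median of -0.69 and 8 lower at an unadjusted p under 0.05. These medians argue against a difference in depth as the whole cause. A part played by depth stays open. With the covariate, the peaks lower at an unadjusted p under 0.05 went from 13 to 8 of 22. Both calls then ended (edgeR adjusted p = 0.13 and 0.14). Their log2 fold changes went from -2.81 ± 0.51 to -2.37 ± 0.64 and from -1.42 ± 0.27 to -1.23 ± 0.34 (SE), so smaller folds and larger errors both contributed. Regional differences between libraries unrelated to the vector may also account for the pattern: in 6 of the 35 splits, the real one included, a window had at least 59.1% of its peaks past an unadjusted p of 0.05. Of the 5 others, 4 had it in a window of chromosome 2, up to 88.2%, and 1, which places control 1 with the Runx3 libraries, had 63.6% in this same window.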

How the results depend on the processing

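Settings named here with the library sets, the 54 peaks or depth, and DESeq2 on the edgeR peaks, were added after the data were seen. No called peak changed direction in a setting that tested it, but as the groups of all 42 do not overlap, leaving out libraries or using 1 set could not have turned one. The counts of 19 higher and 23 lower stayed within 1.5 times without TMM, with median-ratio factors or loess offsets, with a log2 fold change of at least 1, without X and Y, with the set as a term and without the 54 peaks. Fewer were called with DESeq2 (2 and 1; 5 and 1 on the edgeR peaks), limma-voom (5 and 0, with 4560 peaks at an unadjusted p under 0.05), no robust estimation (8 and 10) and thinning to the smallest total (5 and 4). A mean count of at least 50 gave 0 and 0 (858 at an unadjusted p under 0.05), where only 3 of the 42 peaks remained to be tested. More were called at an adjusted p under 0.10 (41 and 50), with no low-count filter (41 and 32), and with the total count as a covariate (33 and 51), although only 13 of the 42 were then past the threshold. Set 1 alone gave 5 and 18, set 2 alone 29 and 72, and the set term without control 1 gave 69 and 195. Leaving out 1 library gave from 0 to 73 higher and from 0 to 194 lower. The extremes were 0 and 0 without control 2 or Runx3 1, and 73 and 194 without control 1, and all 42 were among the latter. Without control 3 there were 4 and 1, without Runx3 4 5 and 2, without Runx3 3 28 and 4, and without control 4 37 and 25. The cause of these shifts was not tested.

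With the replicate number as a block, 30 peaks were higher and 71 lower, and 35 of the 42 were among them. Control 2 has no Runx3 library of its number, so it did not inform the vector effect in this fit. Leaving control 2 out without a block gave 0 and 0. The deviations of same-numbered libraries correlated at 0.117, 0.099 and 0.066, and control 4 correlated better with Runx3 3 (0.087) than with Runx3 4, so the numbers were not taken as pairs. Windows of 500 kb also had 0 past the threshold, and none held more than 1 called peak of the same direction. Over all peaks 0 chromosomes passed, as the exact test could not have reached it. The GC correction, gene sums, gene lists, motifs, promoter split and Runx3 locus were planned and not run, for want of a matching genome.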

Other observations

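The tests in this part were chosen after the results they bear on had been seen, apart from the fit by vector itself.

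On chromosome 8, 21 tested peaks stood in an evenly spaced row between 126113509 and 126148009, with a median spacing of 1702 bases (SD 68.5). It was picked as the longest such row in the 1 Mb windows whose levels varied most between libraries. All 21 had lower fitted levels with Runx3 (median log2 fold change -0.49), 12 at an unadjusted p under 0.05, and 0 passed the adjusted threshold in edgeR. Peaks of this row varied together, so the 21 and the 12 are not separate observations. Their summed level was 976 CPM in control 3, 658 in control 4, 567 in control 2 and 484 in control 1, against 550, 444 and 432 in Runx3 3, 1 and 4, so the groups overlapped. On chromosome 2, the 17 tested peaks between 175000001 and 176000000 also varied together, with a median log2 level relative to the mean of all libraries of 0.47 in control 3, -0.25 in control 1, 0.14 in Runx3 3 and -0.41 in Runx3 4, so they did not follow the vector.

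Chance was not excluded for the number of called peaks. Of the 35 splits of the libraries into 3 and 4, 3 called as many as the real 42, the real one included, and the highest other called 88. That split separates set 1 from set 2, and 43 of its 88 peaks are among the 54 described above. The other, with 84, places control 1 with the Runx3 libraries and otherwise keeps the real grouping. With the set as a term, 4 of the 34 splits that could be fitted called as many as the real 51, and the highest other called 99. This may reflect control 1 standing apart, since that highest split again places it with the Runx3 libraries. That split otherwise keeps the real grouping, so its calls may also reflect the vector contrast. The number of calls cannot tell these readings apart.

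Differences between libraries unrelated to the vector are a candidate explanation for the match in direction between the sets. Of the 101 peaks called in set 2, 79.2% had the same direction when Runx3 1 was set against the controls of set 1. Setting control 1 or control 2 against the rest of set 1 gave 55.4% and 15.8%, and the latter is 84.2% in the opposite direction, so that by the larger of matching and opposite the contrast of Runx3 1 ranked 2. The contrasts use the same 3 libraries and are not independent: where Runx3 1 matches, a control tends the opposite way, also under a vector effect. They therefore give no level expected by chance and the test does not decide. The 2 other ways of dividing set 2 into pairs called 0 peaks in edgeR.

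Another hypothesis is that changes extend beyond single peaks. Of the 42 called peaks, 30 had another tested peak within 50 kb, and for 22 of them the median of those neighbours moved the same way. The median signed log2 fold change of the neighbours was 0.103. Random draws from 4735 peaks with an unadjusted p under 0.05 that were not called gave a median of 0.031. The one-sided p by resampling of peaks was 0.0106 over 10000 draws, in which the vector groups stayed fixed. Change shared by peaks within 50 kb may account for this, whether it comes from the vector or from regional differences between libraries. The draws treat peaks as independent and were not matched to the called peaks in fold size or accessibility, so the p-value does not allow for these.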
